A study of Homo sapiens with 24 samples.

How the data were processed

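Human ECFCs from umbilical cord blood were encapsulated in hydrogels, held in hypoxic or non-hypoxic conditions for 40 min, 10 h or 24 h, and lysed on the gel with Trizol for RNA, per the labels' protocols. Libraries were made with a kit for stranded total RNA, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, Partek (with no version) and the builds GRCh38.p13 and hg38; the aligner, the gene annotation, the counting step and the treatment of zeros are not given in the sources used here.

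The deposited table holds log2 signals, quantile-normalized by the authors, per its title and its values: the library medians all lie between 1.351 and 1.353, and values run from -10.12 to 11.32. The linear unit before the log2 is not stated, so a level is read only against other values of this table. Quantile normalization gives every library the same distribution, so a change shared by most genes would not show. Of 53615 genes listed, 35712 are blank in every library, 17903 have a value in at least 1 and 12906 in all 22. Of the genes with values that match RefSeq by symbol, 98.6% are protein-coding, and only 165 of 11360 listed long non-coding genes have a value. The mitochondrial transcripts and nuclear-retained RNAs chosen as signs of RNA quality have none and could not be tested. Counts and depth cannot be had from the table, so no counting interval is given.

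Groups and replicate numbers came from the treatment label and the sample titles. The titles carry 30 where the treatment label says 40 min, and the treatment label was used. Of 24 samples 22 matched a column; the other 2 were not analysed here. The labels do not say that replicates came from separate cultures or donors, so p-values measure the spread between these samples, which may be technical.

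Genes were tested with limma 3.58.1 in R 4.3.3 on the log2 values as deposited: 1 mean per group in 6 groups over all 22 libraries, contrasts, and eBayes with a trend of the variance with the mean, two-sided, called at a Benjamini-Hochberg adjusted p under 0.05. Genes entered when their mean was at or above the 25th percentile of gene means (13427 genes, lowest mean -4.63) and when each group of the contrast had at least 2 values. The tests, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined; how to treat blanks was decided once the table had been seen, and blank cells were left out. The 9 comparisons were hypoxia against non-hypoxia at 3 times, 2 differences of that effect between successive times, and 4 comparisons of successive times within a condition. An adjusted p in the text is from limma.

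Of 32 gene lists 28 had at least 5 complete genes for a set test with camera in limma, at a preset correlation of 0.01 between genes, on the 12610 complete genes passing the filter; no list passed in any comparison when the correlation was estimated. NADPH oxidase genes and blood markers were too few for the set test. Named genes are, for each oxygen comparison, those with the largest rises and falls among called genes whose hypoxic libraries all lay above or all below the non-hypoxic ones, the called members of each list with the smallest adjusted p, and HIF1A, EPAS1, ARNT, VEGFA, CA9, SLC2A1, PDK1 and EGLN3 whatever their call. For other comparisons they are the largest rises and falls. Unnamed, antisense and non-coding loci were left out of the largest changes, and genes of the Y chromosome and of X inactivation from all tables. List members other than the 4 with the smallest adjusted p appear only where they were named at another time.

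Of the blood markers only CD68 had a mean above 0 (2.00, in 22 libraries); PTPRC had values in 4 libraries. Of markers of fibroblasts, mural and epithelial cells, RGS5 (5.95), KRT18 (6.56), KRT19 (2.74) and KRT8 (2.01) had positive means in 22 libraries, and COL3A1 -1.30.

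Whether replicate numbers pair libraries was checked by correlating the deviations from group means. Every same-numbered pair correlated above 0.1 between hypoxic and non-hypoxic libraries at 40 min (0.191 to 0.493) and between hypoxic libraries at 40 min and 10 h (0.142 to 0.409) and at 10 h and 24 h (0.121 to 0.368), so those numbers were taken to pair the samples. For the other comparisons at least 1 pair was below.

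Alternatives were no filter, a filter at the 50th percentile, a variance prior without trend, 1 added before the log2, only the groups compared, the replicate number as a block, library weights (arrayWeights), centring on ribosomal protein genes, an estimated correlation for lists and leaving out each replicate. Added once the data had been seen were complete genes only, blanks filled with the gene's lowest value, replicate 4 left out of every group, and removal of the trend with transcript length and GC content, with and without the block. That trend was fitted per library with natural splines on the longest transcript of each gene in GENCODE release 29, which covered 97.5% of 13427 genes. Chromosome positions are from the same annotation on GRCh38, 1-based, and span the whole gene.

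The test was checked on simulated data with the real means and spread and 200 changed genes. Of changes of 1 on the log2 scale it recovered 86.6% in each of the 3 oxygen comparisons, 70.1% and 56.7% for the differences of effects (10 h against 40 min and 24 h against 10 h), with 3.85%, 10.4%, 5.52%, 3.39% and 3.60% of calls false. Of changes of 0.5 it recovered 46.3%, 53.7%, 46.3%, 17.9% and 23.9%. The simulated noise was independent between genes and libraries, without the deviations that same-numbered libraries share. These percentages may thus not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.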

Results

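Endothelial colony forming cells (ECFCs), proliferative endothelial cells grown out of human umbilical cord blood, were embedded in hydrogels whose oxygen level can be set and were held under hypoxic or non-hypoxic conditions for 40 min, 10 h or 24 h. Bulk RNA sequencing then measured gene expression at the 3 times. The question was how oxygen changes ECFC gene expression over the hours in which the hypoxic cells gather into clusters, an early step of vessel formation. Values were at hand for 22 of 24 samples. Hypoxic replicate 1 at 40 min and hypoxic replicate 2 at 24 h were not analysed here, which left 3 libraries in each of those groups and 4 in each of the other 4 groups. The values are log2 quantile-normalized signals without counts, so the read depth of the libraries is unknown. Each library had a value for 14466 to 15335 genes. Values below are log2 differences ± the standard error of the fit, or group means ± SD where a level is given.

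Replicates lay close together, with Pearson correlations of 0.980 to 0.994 between libraries of a group across 12906 genes. The mean correlation of hypoxic with non-hypoxic libraries was 0.986 at 40 min, 0.978 at 10 h and 0.954 at 24 h. The first principal component held 54.3% of the variance and ordered the groups by time. The second held 15.6% and parted the oxygen conditions, most widely at 24 h. On that component hypoxic replicate 4 at 24 h scored 20.9, against 40.5 and 48.5 for the other hypoxic libraries of that time and -35.4 to -42.6 for the non-hypoxic ones.

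**Figure D1:**
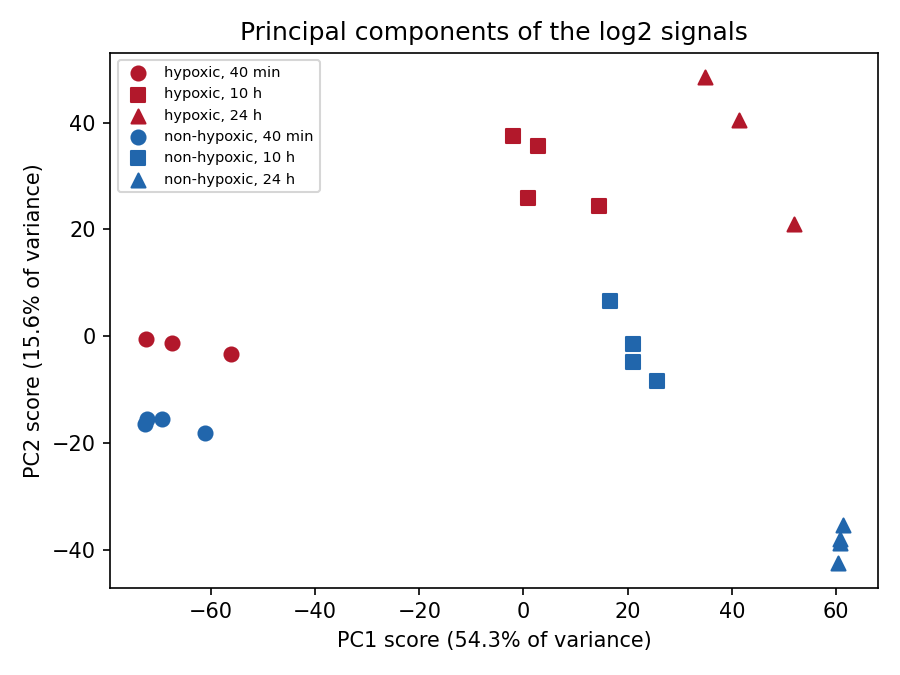
Scores of the 22 libraries on the first principal component (horizontal, 54.3% of variance) and the second (vertical, 15.6% of variance), in arbitrary units. Colour gives the oxygen condition and symbol the time; libraries at 40 min lie at the left, and the hypoxic and non-hypoxic libraries at 24 h lie at the upper and lower right.

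Genes of the hypoxia-inducible factor (HIF) pathway were followed first, since they report on oxygen. VEGFA, the main endothelial growth factor (chromosome 6, 43770184 to 43786487, plus strand), had nearly the same level in both conditions at 40 min, at 1.01 ± 0.26 (SD, n = 4) without and 1.04 ± 0.29 (SD, n = 3) with hypoxia. By 10 h VEGFA stood at 3.74 ± 0.24 in non-hypoxic and 4.44 ± 0.15 in hypoxic gels (SD, n = 4 each), and at 24 h at 2.97 ± 0.11 (n = 4) and 4.03 ± 0.43 (n = 3). SLC2A1, the glucose transporter GLUT1 (chromosome 1, 42925375 to 42959176, minus strand), had a hypoxia difference of 0.09 ± 0.14 at 40 min (adjusted p = 0.727), 0.69 ± 0.13 at 10 h (adjusted p = 0.000446) and 2.57 ± 0.14 at 24 h (adjusted p = 2.35e-11). EGLN3, an oxygen-sensing prolyl hydroxylase that marks HIF for degradation (chromosome 14, 33924231 to 34462774, minus strand), was near the floor at 40 min, with a difference of 0.86 ± 0.41 that did not pass (adjusted p = 0.194; 1.43 and called without hypoxic replicate 2). It differed by 0.54 ± 0.36 at 10 h (adjusted p = 0.242) and 4.06 ± 0.39 at 24 h (adjusted p = 3.33e-08). PDK1, which limits pyruvate entry into mitochondria, was 0.97 ± 0.15 higher in hypoxia at 24 h (adjusted p = 1.63e-05). Its difference at 10 h, 0.36 ± 0.14, did not pass (adjusted p = 0.0519). PDK1 did pass at 10 h without non-hypoxic replicate 2 (0.41) or hypoxic replicate 1 (0.43), and with the length and GC trend removed (0.68). CA9, a carbonic anhydrase, had few values near the floor and was not called at any time (adjusted p = 0.0514 at 24 h).

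The transcripts of the HIF subunits themselves went the other way. HIF1A (chromosome 14, 61695513 to 61748259, plus strand) differed by 0.05 ± 0.12 at 40 min (adjusted p = 0.831) and -0.15 ± 0.11 at 10 h (adjusted p = 0.281), and fell by 0.93 ± 0.12 in hypoxia at 24 h (adjusted p = 1.23e-06). EPAS1, which encodes HIF-2 alpha (chromosome 2, 46293667 to 46386703, plus strand), fell by 0.42 ± 0.14 at 10 h (adjusted p = 0.0221) and by 1.37 ± 0.15 at 24 h (adjusted p = 1.68e-07). The 10 h call of EPAS1 held in 5 of 8 fits that each left out 1 library, and was lost without non-hypoxic replicate 4 (-0.36) or hypoxic replicate 1 (-0.36) or 3 (-0.38). At 40 min its difference of -0.47 ± 0.15 did not pass (adjusted p = 0.0521). It passed with the replicate number as a block, at -0.49, and without hypoxic replicate 4, at -0.69. The latter fit kept non-hypoxic replicate 4, which stood at 5.41 against 4.79 to 4.85 in the other non-hypoxic libraries. That high value widens the EPAS1 difference at 40 min. ARNT, the shared HIF partner, was lower by -0.34 ± 0.09 at 10 h (adjusted p = 0.00571) and -0.37 ± 0.10 at 24 h (adjusted p = 0.00252), and with the length and GC trend removed at -0.16, not called, at 24 h. Every hypoxic library lay beyond every non-hypoxic one for EPAS1, ARNT, VEGFA and SLC2A1 at 10 h and for HIF1A, EPAS1, ARNT, VEGFA, SLC2A1, PDK1 and EGLN3 at 24 h.

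**Figure D2:**
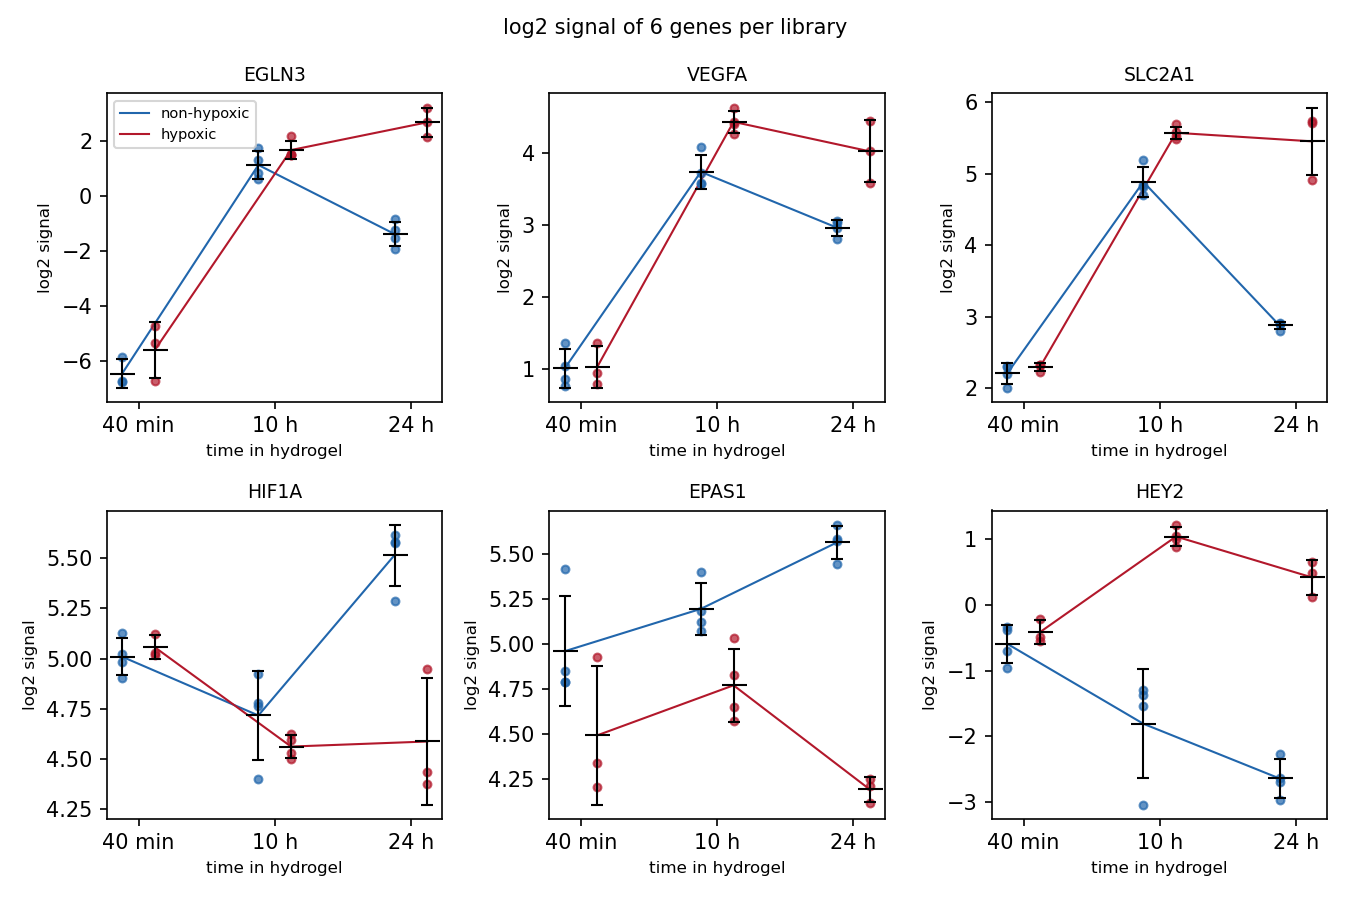
log2 signal (vertical) of EGLN3, VEGFA, SLC2A1, HIF1A, EPAS1 and HEY2 at 40 min, 10 h and 24 h (horizontal). Points are libraries, bars are the mean and SD of each group of 3 or 4 and colour gives the condition. SLC2A1 averaged 2.88 in non-hypoxic and 5.45 in hypoxic gels at 24 h, and HIF1A 5.52 and 4.59.

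The first oxygen comparison asked what differed after 40 min. ENG (endoglin), an endothelial co-receptor for TGF-beta ligands, fell 2.20-fold in hypoxia (standard error 0.15 on the log2 scale, n = 3 against 4, adjusted p = 2.79e-05). NR2F2, the transcription factor of venous identity, fell by 1.00 ± 0.17 (adjusted p = 0.000392). NOTCH1, a Notch receptor, was lower by -0.67 ± 0.13 (adjusted p = 0.00179; -0.35 with the length and GC trend removed). EGR1, an immediate early transcription factor, was lower by -1.27 ± 0.25 (adjusted p = 0.0016), and MKI67, a proliferation marker, by -0.80 ± 0.16 (adjusted p = 0.00177). The mitosis list as a whole averaged 4.64 with and 4.66 without hypoxia. Neither it nor the S phase list passed the set test (adjusted p = 0.897 and 0.685). CXCL3, a neutrophil chemokine, was among the few marked rises, at 1.66 ± 0.28 (adjusted p = 0.000387), from a low level of -3.92 ± 0.84 (SD, n = 4). With 1 added before the log2 it was not called. The largest falls that held with any library left out were in NPIPB12 (-1.98 ± 0.27), ATN1 (-1.96 ± 0.25) and ZNF385A (-1.92 ± 0.27). ATN1 encodes the transcriptional regulator atrophin 1. NPIPB12 belongs to a family of near-identical copies, so its value is uncertain.

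By limma none of the 35 measured HIF targets and none of the 26 glycolysis genes was called at 40 min, over all genes or adjusted over the list alone. Neither list passed the set test (adjusted p = 0.897 and 0.721), and for glycolysis the median, 0.02, and the mean, -0.02, differed in sign. Of 15 targets of YAP, a mechanically regulated co-activator, 5 fell and 10 were not called (7 fell when adjusted over the list alone). Among them were TEAD1, the DNA-binding partner of YAP, at -0.51 ± 0.09 (adjusted p = 0.000776), the matricellular gene CYR61 at -0.95 ± 0.20 (adjusted p = 0.00246) and CRIM1 at -0.40 ± 0.09 (adjusted p = 0.00729). The YAP list passed the set test (adjusted p = 0.0327), but not with an estimated correlation (adjusted p = 0.924), nor with the replicate block (adjusted p = 0.0618). Of 34 extracellular matrix genes 6 fell and 28 were not called (7 fell when adjusted over the list alone), including the laminin chain LAMA5 at -0.76 ± 0.18 (adjusted p = 0.00704). That list did not pass (adjusted p = 0.0646). Of 34 nuclear-encoded respiratory chain genes 6 rose and 28 were not called, the same numbers when adjusted over the list alone. COX7A2, a subunit of cytochrome c oxidase, rose by 0.47 ± 0.11 (adjusted p = 0.00818). This list passed (adjusted p = 0.00276), and did not with an estimated correlation (adjusted p = 0.957). Other splits of the same libraries gave lists past the set test as often, the real split included, in 33 of 35 splits at 40 min, 12 of 35 at 10 h and 19 of 35 at 24 h, so each set p below is descriptive.

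In all, 371 genes rose and 1000 fell of 13014 tested at 40 min, and 9 and 166 of these changed at least 2-fold. The count dropped to 876, 807 and 878 without hypoxic replicate 2, 3 or 4 at that time, and to 903 (147 rose, 756 fell) with replicate 4 left out of every group. Weighting the libraries by their fit gave 4008 (2055 rose, 1953 fell). Longer transcripts were lower in hypoxia (Spearman's rho across genes, which are not independent replicates, -0.327 at 40 min, -0.333 at 10 h and -0.329 at 24 h). After removal of the length and GC trend 2 YAP targets and 1 matrix gene fell, 2 respiratory chain genes rose, no list passed, and COX7A2, LAMA5 and CRIM1 were not called. With replicate 4 left out of every group 2 matrix genes fell and 1 respiratory chain gene rose, and after centring on ribosomal protein genes 3 of the latter rose.

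At 10 h genes of the Notch pathway and of the heat shock response were among the large rises in hypoxia. HEY2, a Notch-induced transcriptional repressor tied to arterial fate (chromosome 6, 125747664 to 125761269, plus strand), was 2.85 ± 0.27 higher (n = 4 each, adjusted p = 3.05e-07). Its relatives HEY1, at 2.04 ± 0.22 (adjusted p = 1.91e-06), and HEYL, at 2.81 ± 0.51 (adjusted p = 0.000272), rose with it. The ligands JAG1 and DLL4 rose by 1.90 ± 0.14 (adjusted p = 1.33e-08) and 1.36 ± 0.19 (adjusted p = 1.86e-05), and GJA4, an arterial connexin, by 3.23 ± 0.58 (adjusted p = 0.000267). The stress-inducible chaperone HSPA6 was 3.08 ± 0.28 higher (adjusted p = 1.67e-07). RFLNA had the largest rise, 4.49 ± 0.46 (adjusted p = 7.79e-06), but rested on 2 non-hypoxic and 3 hypoxic values. Falls were smaller, among them NR2F2 at -1.04 ± 0.16 (adjusted p = 4.31e-05) and PKHD1L1 at -2.11 ± 0.46 (adjusted p = 0.0012).

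Of 20 Notch and arterial genes 12 rose, 4 fell and 4 were not called at 10 h (adjusted p = 0.00156 for the list; adjusted p = 0.34 with an estimated correlation). The count was the same when adjusted over the list alone. Of 29 genes of S phase and DNA replication 24 rose and none fell (26 when adjusted over the list alone), including the helicase subunits MCM2, 1.45 ± 0.14 (adjusted p = 2.49e-07), and MCM6, 1.23 ± 0.10 (adjusted p = 4.87e-08). The list's adjusted p = 3.58e-12 became adjusted p = 0.34 with an estimated correlation. Its mean was 2.99 with and 2.33 without hypoxia, both below the 3.71 and 3.67 at 40 min. Of 27 mitosis genes 2 rose, 4 fell and 21 were not called (2 and 2 when adjusted over the list alone, 1 and 0 with the length and GC trend removed, 6 and 2 with replicate 4 left out). Of 16 heat shock genes 11 rose and 5 were not called (13 rose when adjusted over the list alone; list adjusted p = 2.37e-05, adjusted p = 0.222 with an estimated correlation). HSPA1A and HSPA1B, near-identical copies whose reads can be shared, rose by 2.02 ± 0.17 and 2.06 ± 0.15, and the co-chaperones DNAJB1 and BAG3 by 1.17 ± 0.10 and 0.95 ± 0.09. Of 17 genes of the TGF-beta and BMP response 9 rose and 1 fell, the same when adjusted over the list alone (list adjusted p = 0.0101; adjusted p = 0.602 with an estimated correlation), with the BMP-induced ID1 at 1.19 ± 0.13 and ID3 at 1.30 ± 0.16 and the inhibitor SMAD6 at 1.69 ± 0.25.

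HIF targets and metabolic genes also differed at 10 h. Of 35 HIF targets 13 rose and 2 fell, the same when adjusted over the list alone (list adjusted p = 0.00578; adjusted p = 0.602 with an estimated correlation), such as the vasodilator peptide ADM, 1.11 ± 0.11 (adjusted p = 9.15e-07), and the lipid droplet gene HILPDA, 2.03 ± 0.31 (adjusted p = 4.46e-05). Of 26 glycolysis genes 10 rose and 2 fell (12 and 3 when adjusted over the list alone), with SLC2A3 at 0.89 ± 0.15 and the branching enzyme GBE1 at -0.48 ± 0.09 (list adjusted p = 0.0101; adjusted p = 0.615 with an estimated correlation). Of 34 respiratory chain genes 13 rose (14 when adjusted over the list alone; 7 after centring on ribosomal protein genes, 8 with the length and GC trend removed and 7 with replicate 4 left out) and none fell (list adjusted p = 0.000514), and of 23 genes of cholesterol synthesis 10 rose (12 when adjusted over the list alone) and none fell (list adjusted p = 0.00196), among them mevalonate kinase, MVK, at 1.13 ± 0.19. Both had adjusted p = 0.602 with an estimated correlation. Of 28 immediate early genes 11 rose and 4 fell, the same when adjusted over the list alone (list adjusted p = 0.0156; adjusted p = 0.602 with an estimated correlation), for example NR4A1 at 1.65 ± 0.26. The oxidative stress list was the reverse. Of 27 genes 3 rose and 11 fell, the same when adjusted over the list alone. The set test gave the list adjusted p = 0.0498, against adjusted p = 0.602 with an estimated correlation and adjusted p = 0.0515 with the replicate block. The cystine transporter SLC7A11 stood at -1.25 ± 0.17 and the glutathione synthesis gene GCLM at -0.59 ± 0.09.

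Sprouting genes rose in part: 8 of 21 rose and 4 fell (9 and 5 when adjusted over the list alone), and the list did not pass (adjusted p = 0.0756). The tip cell gene ESM1 rose by 1.71 ± 0.11 (adjusted p = 1.39e-09) and the peptide ligand APLN by 1.51 ± 0.22 (adjusted p = 3.9e-05). Of the markers of other cells, the epithelial keratins KRT8 and KRT18 were higher in hypoxia at 10 h, by 0.46 ± 0.10 and 0.60 ± 0.13, as was the macrophage marker CD68, by 0.46 ± 0.11. The keratins and CD68 had values in all 22 libraries. The epithelial markers EPCAM (mean -3.50, in 20 libraries) and CDH1 (-7.06, in 3) were low, as was the blood marker PTPRC (-7.64, in 4). In all, 2454 genes rose and 2452 fell of 13111 tested at 10 h, and 249 and 178 changed at least 2-fold. Centring each library on ribosomal protein genes changed this to 1723 and 3197, or 35.0% higher.

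**Figure D3:**
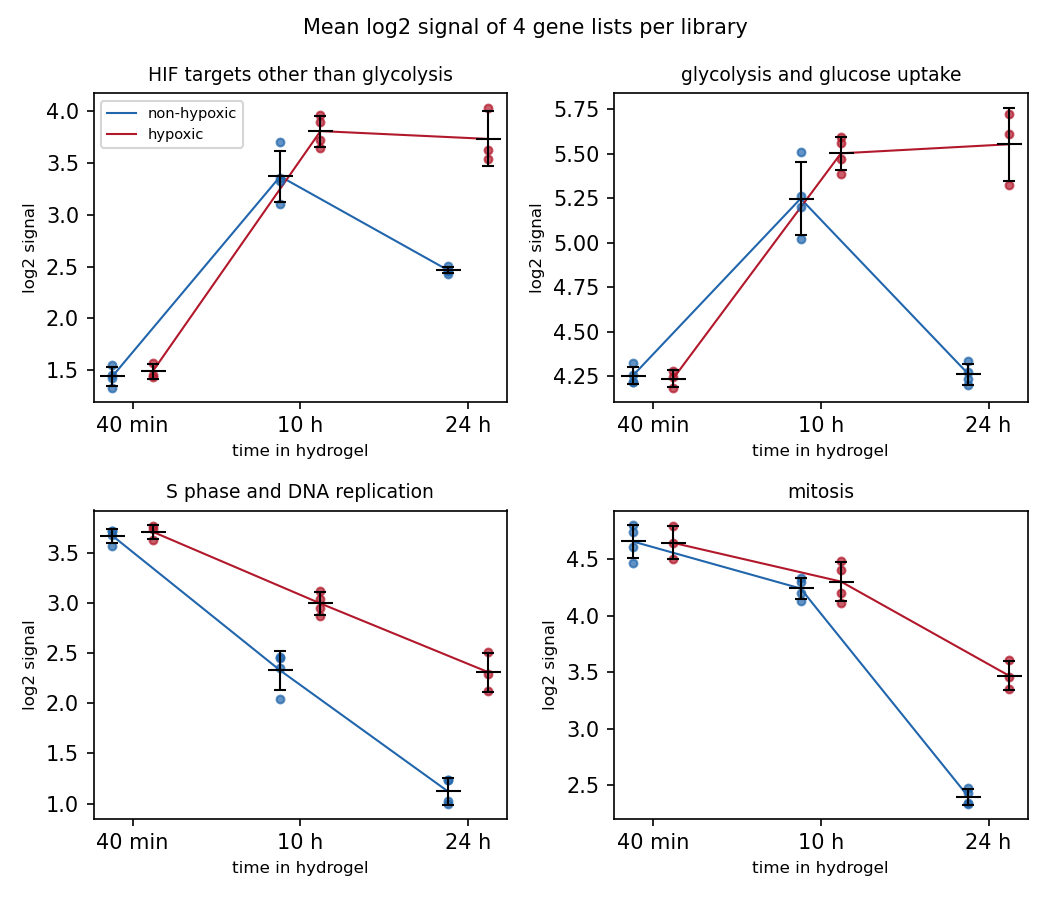
Mean log2 signal (vertical) of 4 gene lists at 40 min, 10 h and 24 h (horizontal) in non-hypoxic (blue) and hypoxic (red) gels. Points are libraries, bars are the mean and SD of each group. The glycolysis list averaged 5.25 without and 5.50 with hypoxia at 10 h, and 4.26 and 5.55 at 24 h.

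At 24 h hypoxic ECFCs expressed far more of the HIF and glycolytic genes. AK4, a mitochondrial adenylate kinase, was 3.57 ± 0.15 higher (n = 3 against 4, adjusted p = 6.75e-13), ANGPTL4, an inhibitor of lipoprotein lipase, 3.93 ± 0.30 (adjusted p = 1.51e-09), and PFKFB4, a regulator of glycolytic flux, 3.73 ± 0.34 (adjusted p = 1.3e-08). LDHA, lactate dehydrogenase A, rose by 1.80 ± 0.09 (adjusted p = 1.15e-11), from 5.85 ± 0.07 (SD, n = 4) to 7.65 ± 0.22 (SD, n = 3). KDR, the main VEGF receptor, fell by 1.87 ± 0.20 (adjusted p = 1.22e-07), NR2F2 by 2.00 ± 0.17 (adjusted p = 4.8e-09), and the interferon gene IFNE by 3.15 ± 0.22 (adjusted p = 4.72e-10).

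Of 35 HIF targets 29 rose, 1 fell and 5 were not called at 24 h (30 rose when adjusted over the list alone), with a median difference of 1.23 (list adjusted p = 4.32e-12). The mitophagy receptor BNIP3 rose by 1.52 ± 0.08 and the collagen hydroxylase P4HA1 by 1.62 ± 0.11. Of 26 glycolysis genes 25 rose and 1 fell, the same when adjusted over the list alone (median 1.15, list adjusted p = 1.58e-14). Cell cycle genes were higher than in non-hypoxic gels as well, though they fell with time in both conditions. From 10 h to 24 h the S phase list went from 2.99 to 2.31 with hypoxia and from 2.33 to 1.12 without. The mitosis list went from 4.30 to 3.47 and from 4.24 to 2.40. All 29 S phase genes rose, also when adjusted over the list alone (median 1.13, list adjusted p = 2.49e-15), with the transcription factor E2F1 at 2.20 ± 0.16 and the helicase subunit MCM7 at 1.44 ± 0.11. Of 27 mitosis genes 24 rose, the same when adjusted over the list alone (median 1.16, list adjusted p = 1.58e-14), with survivin, BIRC5, at 1.50 ± 0.10 and the checkpoint kinase BUB1 at 1.43 ± 0.11. Of 16 heat shock genes 13 rose and none fell, the same when adjusted over the list alone (list adjusted p = 0.000395). These 5 lists had adjusted p = 0.17 with an estimated correlation.

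Smaller shifts at 24 h were in the respiratory chain, where 20 of 34 genes rose and 2 fell (21 and 2 when adjusted over the list alone; list adjusted p = 0.000395, adjusted p = 0.519 with an estimated correlation). In cholesterol synthesis 13 of 23 rose and 1 fell, the same when adjusted over the list alone (list adjusted p = 0.00215, adjusted p = 0.675 with an estimated correlation). Of 17 TGF-beta and BMP genes 7 rose and 1 fell, the same when adjusted over the list alone (list adjusted p = 0.0484, adjusted p = 0.519 with an estimated correlation). The Notch list did not pass (adjusted p = 0.0612) although 11 of 20 genes rose and 5 fell (12 and 5 when adjusted over the list alone). HEY2 was up by 3.06 ± 0.29 and HES1 by 1.60 ± 0.15, and the receptor NOTCH2 down at -1.37 ± 0.09 (-0.79 with the length and GC trend removed). Of 27 oxidative stress genes 15 fell and 5 rose, the same when adjusted over the list alone (list adjusted p = 0.0612). SLC7A11 stood at -1.85 ± 0.18. Among 31 endothelial identity genes 6 rose and 8 fell, the same when adjusted over the list alone (10 and 8 with replicate 4 left out; list adjusted p = 0.996, median -0.05 with a test direction up). Of 30 proteases and inhibitors 8 rose and 14 fell (11 and 14 when adjusted over the list alone; list adjusted p = 0.899, median 0.03 with a test direction down), with tissue plasminogen activator, PLAT, 2.55 ± 0.18 higher and cathepsin L, CTSL, at -1.19 ± 0.11. VCAM1, a leukocyte adhesion molecule, rose by 2.48 ± 0.41 (adjusted p = 2.46e-05), while 7 of 28 inflammation genes rose and 6 fell, the same when adjusted over the list alone (7 and 9 with replicate 4 left out; list adjusted p = 0.746).

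Keratin genes were again higher in hypoxia at 24 h (KRT19 by 1.23 ± 0.24, KRT18 by 0.60 ± 0.14 and KRT8 by 0.49 ± 0.10). In all, 3130 genes rose and 3871 fell of 13071 tested at 24 h, and 703 and 1094 changed at least 2-fold. Hypoxic replicate 4 was the lowest of its group for the glycolysis list, at 5.32 against 5.61 and 5.72, and the mitosis list, at 3.35 against 3.46 and 3.60. With replicate 4 left out of every group 2969 genes rose and 4298 fell, and 29 HIF targets, 25 glycolysis, 29 S phase and 24 mitosis genes rose.

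**Figure D4:**
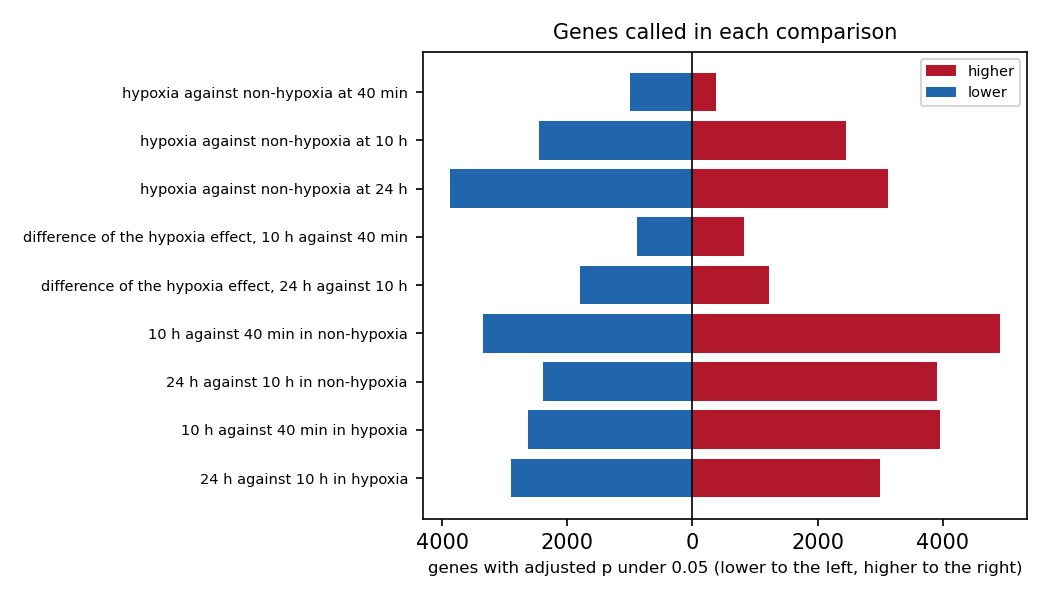
Genes with adjusted p under 0.05 in each comparison (horizontal: number lower in blue to the left and higher in red to the right). At 40 min 371 genes were higher and 1000 lower in hypoxia, at 24 h 3130 and 3871.

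The oxygen effects of the 3 times shared no libraries, so their overlap is free of shared controls. It is not free of the transcript length trend common to the 3 times. Nor is it free of deviations shared by hypoxic libraries of the same number at successive times. The 3 comparisons also share the spread of each gene, estimated over all 22 libraries, so genes of small spread are called more easily at each time. The numbers for independent lists leave all of this out. Of 2448 genes higher at 10 h and 3129 higher at 24 h, 1461 were the same genes, where 587 would be shared by independent lists. Of 2452 and 3871 lower genes 1756 were shared (728 if independent). Between 40 min and 10 h 95 higher genes (69.8 if independent) and 524 lower genes (189 if independent) were shared. The log2 differences correlated across genes with r = 0.603 between 10 h and 24 h, 0.262 between 40 min and 10 h and 0.308 between 40 min and 24 h.

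Whether the oxygen effect itself changed with time was tested as a difference of differences. From 40 min to 10 h the hypoxia effect on HSPA6 grew by 3.29 ± 0.41 (adjusted p = 4.71e-05) and that on HEYL by 3.54 ± 0.74 (adjusted p = 0.00507), and the effect on SLC2A1 by 0.60 ± 0.19 (adjusted p = 0.045). The effect on CYP1A1, a xenobiotic oxidase, turned down, by -2.30 ± 0.57 (adjusted p = 0.0122), and was not called without hypoxic replicate 4 at 40 min (-1.83). Of 29 S phase genes 17 shifted up (20 when adjusted over the list alone; list adjusted p = 4.45e-11, adjusted p = 0.251 with an estimated correlation). So did 11 of 20 Notch genes (12 when adjusted over the list alone; list adjusted p = 1.89e-05, adjusted p = 0.101 with an estimated correlation) and 7 of 15 YAP targets (8 when adjusted over the list alone; list adjusted p = 0.000945, adjusted p = 0.101 with an estimated correlation). Of 27 oxidative stress genes 7 shifted down and 2 up (10 and 2 when adjusted over the list alone; list adjusted p = 0.00873, adjusted p = 0.646 with an estimated correlation). In all 827 genes shifted up and 883 down of 12986 (618 and 1167 after centring on ribosomal protein genes, 34.6% higher against 48.4%). The total of 1710 became 924 without hypoxic replicate 4 at 40 min, 1125 without hypoxic replicate 2 at 10 h, 3598 with library weights and 3153 with the length and GC trend removed and the replicate block.

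From 10 h to 24 h the effect grew in glycolytic and mitotic genes, among others. The glycolysis list mean fell from 5.25 to 4.26 in non-hypoxic gels and was 5.50 and 5.55 in hypoxic ones. The mitosis list mean fell in both, to 2.40 without and 3.47 with hypoxia. AK4 shifted by 3.60 ± 0.21 (adjusted p = 3.61e-10), EGLN3 by 3.52 ± 0.53 (adjusted p = 8.97e-05), ANGPTL4 by 3.31 ± 0.41 (adjusted p = 1.06e-05) and PTGIS, prostacyclin synthase, by 3.29 ± 0.43 (adjusted p = 1.87e-05). KIF19, a kinesin, shifted by -3.78 ± 0.57 (adjusted p = 7.46e-05) and KSR2, a kinase scaffold, by -2.99 ± 0.42 (adjusted p = 4.21e-05). Of 27 mitosis genes 26 shifted up (27 when adjusted over the list alone; median 1.02, list adjusted p = 4.18e-23), and of 26 glycolysis genes 21 (22 when adjusted over the list alone; median 0.93, list adjusted p = 1.53e-18). Of 35 HIF targets 20 shifted up and 1 down (24 and 1 when adjusted over the list alone; list adjusted p = 1.38e-11) and of 29 S phase genes 15 up and 1 down (16 and 1 when adjusted over the list alone; list adjusted p = 2.57e-07). With an estimated correlation these were adjusted p = 0.106, 0.106, 0.252 and 0.711. In all 1225 genes shifted up and 1801 down of 13042. The split turned to 1629 and 1347 after centring on ribosomal protein genes (54.7% higher against 40.5%) and to 1959 and 1532 after removal of the length and GC trend.

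Changes with time within non-hypoxic gels were larger than the oxygen effects at 40 min and 10 h in number. From 40 min to 10 h EGLN3 rose by 7.58 ± 0.39 (n = 4 at 10 h and 3 at 40 min, adjusted p = 1e-12), from near the floor, and HMOX1, heme oxygenase 1, by 6.68 ± 0.12 (adjusted p = 5.03e-21), to 10.7 to 10.9 in every library. At those values HMOX1 was among the highest ranks of a library, where quantile normalization leaves little room to vary. SELE, an adhesion molecule of activated endothelium, rose by 6.36 ± 0.67 (adjusted p = 3.33e-08), and the chemokine CXCL3 by 6.37 ± 0.26 (adjusted p = 1.31e-14). APLN fell by 3.74 ± 0.22 (adjusted p = 4.97e-12), ANKRD1, a YAP target, by 3.80 ± 0.13 (adjusted p = 1.46e-15) and FOS by 3.70 ± 0.20 (adjusted p = 1.37e-12).

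In these non-hypoxic gels 30 of 35 HIF targets rose from 40 min to 10 h and none fell, the same when adjusted over the list alone (median 2.01, list adjusted p = 8.03e-11; adjusted p = 0.287 with an estimated correlation). Of 20 p53 targets 18 rose (list adjusted p = 6.81e-06). Of 26 inflammation genes 20 rose and 3 fell (list adjusted p = 0.00013) and of 27 oxidative stress genes 19 rose and 4 fell (list adjusted p = 0.000479), each the same when adjusted over the list alone. These 3 lists had adjusted p = 0.342 with an estimated correlation. All 29 S phase genes fell, also when adjusted over the list alone (median -1.26, list adjusted p = 7.01e-15; adjusted p = 0.287 with an estimated correlation). So did 18 of 23 cholesterol genes, the same when adjusted over the list alone (list adjusted p = 1.56e-05; adjusted p = 0.443 with an estimated correlation), and 11 of 15 YAP targets (12 when adjusted over the list alone; list adjusted p = 7.33e-05; adjusted p = 0.116 with an estimated correlation). In all 4911 genes rose and 3338 fell of 13052 (3929 and 4669 after removal of the length and GC trend). Centring on ribosomal protein genes moved the median of all genes by -0.10 in this comparison, by -0.18 from 10 h to 24 h in non-hypoxic gels, and by -0.14 and -0.10 in the matching hypoxic comparisons. After it 28 HIF targets rose and 29 S phase genes fell from 40 min to 10 h.

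From 10 h to 24 h HIF targets turned back in non-hypoxic gels, while S phase genes fell further. AK4 fell by 3.41 ± 0.14 (n = 4 each, adjusted p = 2.12e-13), PFKFB4 by 3.69 ± 0.32 (adjusted p = 3.03e-09) and VCAM1 by 3.07 ± 0.38 (adjusted p = 6.78e-07). BEX2 rose by 3.65 ± 0.39 (adjusted p = 1.21e-07) and the decoy interleukin receptor IL13RA2 by 3.49 ± 0.45 (adjusted p = 1.97e-06). Of 35 HIF targets 27 fell and 2 rose (28 and 2 when adjusted over the list alone; list adjusted p = 2.67e-10), and of 26 glycolysis genes 22 fell and 2 rose, the same when adjusted over the list alone (list adjusted p = 2.7e-12). All 27 mitosis genes fell, also when adjusted over the list alone (median -1.83, list adjusted p = 8.8e-31), and 26 of 29 S phase genes with 1 rise, the same when adjusted over the list alone (list adjusted p = 3.42e-17). With an estimated correlation these were adjusted p = 0.259, 0.24, 0.0778 and 0.224. In all 3898 genes rose and 2388 fell of 13111, a split that became 2207 and 3808 after centring on ribosomal protein genes (36.7% higher against 62.0%) and 3375 and 3141 after removal of the length and GC trend.

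Hypoxic gels shared the first rise. From 40 min to 10 h HSPA6 rose by 8.83 ± 0.30 (n = 4 against 3, adjusted p = 2.39e-15), EGLN3 by 7.27 ± 0.39 (adjusted p = 3.82e-12), HMOX1 by 6.84 ± 0.13 (adjusted p = 1.63e-20) and the cytokine LIF by 5.95 ± 0.51 (adjusted p = 3.36e-09). The vasoconstrictor EDN1 fell by 3.25 ± 0.21 (adjusted p = 2.6e-11). Of 35 HIF targets 32 rose and none fell, the same when adjusted over the list alone (median 2.14, list adjusted p = 1.93e-18; adjusted p = 0.176 with an estimated correlation). Of 29 S phase genes 25 fell, the same when adjusted over the list alone (median -0.78, list adjusted p = 1.11e-09; adjusted p = 0.393 with an estimated correlation). In all 3948 genes rose and 2630 fell of 13025, which became 2948 and 3827 after centring on ribosomal protein genes (43.5% higher) and 3098 and 4107 after removal of the length and GC trend.

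From 10 h to 24 h the hypoxic gels kept no common direction in the HIF list. Of its 35 genes 9 rose and 11 fell (10 and 13 when adjusted over the list alone), and of 26 glycolysis genes 8 rose and 7 fell, the same when adjusted over the list alone. Neither list passed (adjusted p = 0.981 and 0.705). With replicate 4 left out of every group 9 glycolysis genes rose and 1 fell (median 0.14), against 11 rises and 9 falls among 34 HIF targets. HEYL fell by 3.28 ± 0.55 (n = 3 against 4, adjusted p = 6.25e-05) and the Wnt inhibitor DKK2 by 3.54 ± 0.56 (adjusted p = 7.82e-05). CHPF, a chondroitin synthase, rose by 3.42 ± 0.39 (adjusted p = 3.3e-06) and NEFM, a neurofilament, by 3.10 ± 0.49 (adjusted p = 3.3e-05). All 27 mitosis genes fell, also when adjusted over the list alone (median -0.82, list adjusted p = 1.56e-13), as did 21 of 29 S phase genes with 1 rise (22 and 1 when adjusted over the list alone; list adjusted p = 1.08e-07). Both had adjusted p = 0.885 with an estimated correlation. In all 2994 genes rose and 2898 fell of 13079, which became 2229 and 3838 after centring on ribosomal protein genes (36.7% higher against 50.8%).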

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

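Of the tests in this part, the correlation of replicate 4 across times and the removal of the length and GC trend were chosen after the result was seen. Sets of 4 values, each for 1 gene or list in 1 group, were checked for a wide gap relative to their range. In 4 of 45 sets 1 library lay apart from the other 3, not clearly above the 1 in 20 of chance. These were EPAS1 in non-hypoxic replicate 4 at 40 min (5.41, others 4.79 to 4.85), EGLN3 in hypoxic replicate 4 at 10 h (2.18, others 1.49 to 1.54), HIF1A in non-hypoxic replicate 4 at 24 h (5.29, others 5.58 to 5.61) and SLC2A1 in non-hypoxic replicate 2 at 24 h (2.80, others 2.90 to 2.91).

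The oxygen effect differed between times, by a test of the difference itself, in 1710 genes from 40 min to 10 h and in 3026 genes from 10 h to 24 h. From 40 min to 10 h the largest were RFLNA (4.32), INHBB (3.74), HEYL (3.54), DLX2 (3.40), HSPA6 (3.29) and CILP2 (2.98) upward and TMEM56-RWDD3 (-2.93), PKHD1L1 (-2.49), ZNF396 (-2.31), CYP1A1 (-2.30), FER1L6 (-2.24) and NKAPL (-2.22) downward, and SLC2A1 shifted by 0.60. From 10 h to 24 h they were AK4 (3.60), EGLN3 (3.52), PPFIA4 (3.35), ANGPTL4 (3.31), PTGIS (3.29) and LEFTY1 (3.28) upward and KIF19 (-3.78), ZNF485 (-3.60), KSR2 (-2.99), INHBB (-2.99), PRPH2 (-2.98) and OR1B1 (-2.90) downward. Of the HIF genes, HIF1A shifted by -0.77, EPAS1 by -0.95, SLC2A1 by 1.89 and PDK1 by 0.61.

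Splits of the same libraries into groups of the same sizes were compared with the real split. Only the real one of 35 gave as many genes at 10 h (4906, highest other 77) and at 24 h (7001, highest other 4615). The same held between times in non-hypoxic gels (8249, highest other 2, and 6286, highest other 3). The share of 1 of 35 is under 0.05 but is the smallest these splits can give. If numbers do not pair libraries, it argues against chance at 24 h and from 10 h to 24 h in non-hypoxic gels. Same-numbered libraries correlated at 0.088, 0.075 and -0.128 in the first and at 0.215, -0.051, 0.159 and 0.118 in the second. With pairing, only 8 splits would part all pairs, too few to exclude chance. At 10 h and from 40 min to 10 h in non-hypoxic gels, the lowest same-number correlations were just under 0.1 (0.0962 and 0.0980). If the numbers pair those libraries, only 8 splits part all 4 pairs, too few to exclude chance (highest other 1 and 0). At 40 min and between times in hypoxic gels replicate numbers pair the libraries, and only 8 splits part all 3 pairs as the real one does, too few for a share under 0.05. Of these the real one gave 1371 (highest other 107), 6578 (highest other 3864) and 5892 (highest other 1987). The others part fewer pairs, and over all splits 1 of 35 gave as many in each (highest other 449, 4385 and 3582). The high ones at 24 h and in hypoxic gels exchange nearly all labels and are close to mirror images of the real split. For the differences of effects the splits could not decide. Exchanging labels within a time removes the oxygen effect itself, not only its change with time. Of the splits that part as many pairs, 1 of 70 gave at least 1710 (highest other 994) and 1 of 100 fitted at least 3026 (highest other 2737). Of all splits, 3 of 100 drawn gave at least 1710 (highest other 2376) and 4 of 100 at least 3026 (highest other 4389). The higher ones part fewer pairs and exchange all or many of the labels at 10 h. For the number of gene lists past the set test at its preset correlation, chance could not be excluded. As many lists passed in 33 of 35 splits at 40 min (2 lists, highest other 13), 12 of 35 at 10 h (10, highest other 19) and 19 of 35 at 24 h (8, highest other 11).

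At 40 min more of the called genes fell than rose in hypoxia, 72.9% of 1371. The median difference over all 13014 genes tested was 0.06 (0.02 after centring on ribosomal protein genes). The excess of falls was thus one of the called genes, not of all genes. Removing the trend with transcript length and GC content left 73.2% of 1241 lower, and with the replicate block 63.9% of 1887 (block alone 65.1% of 1944), which argues against that trend as the whole cause. In fits that left out 1 library at least 67.0% were lower, but without hypoxic replicate 2, 3 or 4 only 876, 807 and 878 genes were called, so a part played by single libraries stays open. Library weights left 48.7% of 4008 lower. An early fall of transcripts under low oxygen is a hypothesis that was not tested, and would need counts with a spike-in.

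From 40 min to 10 h HIF targets rose in non-hypoxic gels as well, with a median of 2.01. If hypoxic RNA in the non-hypoxic libraries at 10 h were the only change since 40 min, all genes would lie the same fraction of the way to the hypoxic level. HIF targets (0.731, 28 genes) and Notch genes (0.212, 9 genes) differed by 0.519 (permutation p = 0.00433), which argues against mixing as the only change. Since 8249 of 13052 genes changed in non-hypoxic gels over that time, fractions could differ with or without mixing. Whether some hypoxic RNA was present thus stays undecided. After centring on ribosomal protein genes the median was 1.91, so the rise did not rest on an offset of whole libraries from those genes. The centring moved all genes of a library alike and started from normalized values. It could not test other effects of quantile normalization. That cells used up oxygen within the non-hypoxic gels is a hypothesis left open, and oxygen read inside both gels over time would test it.

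Hypoxic replicate 4 at 24 h lay between its group and the non-hypoxic libraries. Were it mixed with non-hypoxic RNA, all gene sets would lie about the same fraction of the way. The median was 0.393 for glycolysis and 0.182 for mitosis genes, the widest gap of 5 sets at 0.210. These fractions set a single library against the mean of the others of its group, and the spread between libraries was not measured. The gap therefore cannot decide on a mixture. Its deviations from the group mean correlated with those of replicate 4 in the hypoxic groups at 40 min (0.241) and 10 h (0.368). Non-hypoxic and hypoxic replicate 4 correlated at 40 min (0.493) and 10 h (0.257) but not at 24 h (-0.128). How far a structure shared by libraries numbered 4 reaches thus stays open, and what that number stands for is not stated. A different stage of the response in that culture stays open and was not tested.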

How the results depend on the processing

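The alternatives added once data were seen were complete genes, filled blanks, replicate 4 left out and the length and GC trend removed. Of 395 results for named genes 303 kept their call under every alternative, fits without 1 library included, and 414 of 8040 values changed it. In 2866 of 3084 fits without 1 library the call was the same, in 214 it was lost and in 4 gained. The direction turned for RPS9 at 10 h with the length and GC trend removed (-0.0038, with or without block), AMOTL1 at 24 h with trend and block (0.0081) and RPL10A at 24 h (-0.041, with block -0.044). The cause was not tested.

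The count at 40 min moved from 1371 to 4008 with library weights and 903 with replicate 4 left out of every group, and the difference from 40 min to 10 h from 1710 to 3598 with library weights and 3153 with the trend removed and the block; the cause was not tested. Lists past the set test at 40 min went from 2 to 0 with an estimated correlation and with the trend removed, with or without block, and to 1 with the block, with centring on ribosomal protein genes and with replicate 4 left out. With an estimated correlation 0 lists passed at 10 h and 0 at 24 h, and 0 in each other comparison. Other totals of called genes, and of lists past the set test at the 3 times, stayed within 1.5 times in fits of all libraries or without replicate 4, while counts by direction or within a list moved more in places.

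Leaving out each library in turn gave 807 to 1370 genes at 40 min (876, 807 and 878 without hypoxic replicates 2, 3 and 4), 3520 to 4898 at 10 h and 5998 to 7081 at 24 h. For the differences it gave 924 to 1973 (924 without hypoxic replicate 4 at 40 min, 1125 without hypoxic replicate 2 at 10 h) and 2485 to 3572. Within non-hypoxic gels it gave 7685 to 8085 and 5530 to 5917, within hypoxic gels 5486 to 6281 and 5245 to 5610. Lists ranged from 1 to 6 at 40 min (4 without non-hypoxic replicate 3 or 4, 6 and 1 without hypoxic replicates 2 and 3), 8 to 11 at 10 h and 7 to 11 at 24 h.

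With the replicate number as a block the counts were 1944, 5637 and 7440 at the 3 times, 2556 and 3707 for the differences, 8647 and 6790 in non-hypoxic and 7017 and 6300 in hypoxic gels, with 1, 10 and 9 lists. Where the numbers pair the samples, the block changed the calls of EPAS1 and the YAP list at 40 min and no other named gene or list of the oxygen comparison. Elsewhere at least 1 pair correlated below 0.1. There the block ended the set test call of the oxidative stress list at 10 h (adjusted p = 0.0515). It added the extracellular matrix list at 10 h (adjusted p = 0.0224) and the fibroblast, mural and epithelial markers at 24 h (adjusted p = 0.0281). Errors of block fits are approximate for genes with blanks. Depth is unknown, so what it limits could not be measured.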

Other observations

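The 2 gene families here were chosen once the data had been seen, so the comparison with random lists below is descriptive. Random lists also leave out the correlation between genes. Zinc finger genes named ZNF, mostly repressors of transcription, were lower in hypoxia at 10 h. Of 467 22 rose and 191 fell, with a median of -0.32, below all of 10000 random lists matched in number and mean signal (95% range -0.01 to 0.08). At 24 h 63 of 466 rose and 199 fell, with a median of -0.30 (-0.14 with the length and GC trend removed). At 40 min 15 rose and 22 fell, but the median of 0.13 lay above the range of random lists (0.04 to 0.11), and at 0.07 with the length and GC trend removed it did not (0.03 to 0.08). From 40 min to 10 h 283 rose and 47 fell in non-hypoxic gels and 157 rose and 79 fell in hypoxic gels (116 and 114 after centring on ribosomal protein genes).

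Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, went against the S phase genes at 10 h. None of 68 rose and 48 fell in hypoxia by limma, with a median of -0.48. From 10 h to 24 h 64 fell in non-hypoxic gels (median -1.51) and 60 fell and 1 rose in hypoxic gels (median -0.94). At 24 h 11 were higher and 8 lower in hypoxia, with a median of 0.13 that became -0.01 with the length and GC trend removed.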
